A study of Mus musculus with 4 samples.

How the data were processed

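The data were 4 Affymetrix Mouse430_2 arrays, each hybridised with amplified RNA from whole mouse kidneys at embryonic day 14.5 (Theiler stage 22). Per the labels, 2 arrays held wild-type kidneys and 2 held kidneys from embryos null for Wnt4, a secreted signalling protein of the developing kidney. Each wild-type array held RNA from a pool of 2 kidneys and each mutant array RNA from a pool of 12 kidneys. The strain field gave CD-1 for the wild-type arrays and 129 for the mutant arrays, while the protocol text, which was the same for all arrays, described matings of CD-1 mice. Genotype, stated strain and pool size therefore changed together, and none of them could be a covariate. The labels call each pool a biological replicate. They do not say whether the 2 pools of a genotype came from separate litters, so p-values measure the spread between these pools. Per the labels' protocols, RNA was isolated with a column kit, amplified in 1 round and labelled with biotin.

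The values analysed were the authors' processed values, 1 deposited signal intensity per probe set and array on a linear scale. GCOS, the scanner maker's software, is the only tool named in the submitters' processing notes, with no version given, and the summary algorithm and the scaling target are not given in the sources used here. After the lowest and highest 2% of the values were trimmed, the mean was 499.9 on each of the 4 arrays after rounding, so the arrays had been scaled to a common level before deposit. The median signal was 150.9 and 148.9 on wild-type replicates 1 and 2 and 137.5 and 159.3 on mutant replicates 1 and 2. The 3' to 5' signal ratio of the Gapdh control ranged from 0.744 to 0.777 and that of the actin control from 1.43 to 1.59. That of the transferrin receptor control was 4.71 and 5.10 on the wild-type arrays and 5.67 and 6.43 on the mutant arrays. The bioB hybridisation control, as a percentage of the cre control, read 3.62% and 4.51% on the wild-type arrays and 2.97% and 2.93% on the mutant arrays. Detection calls were not used here. The number of arrays limits the precision: an exact test of 2 arrays against 2 cannot give a two-sided p below 0.33, so tests that share information across probe sets were used.

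Signals were transformed to log2(signal + 16) without further normalization. The 64 AFFX control probe sets were left out, and so were the probe sets in the lowest 40% by mean log2 value over the 4 arrays, which left 27022 of 45101. The lowest mean level kept corresponded to a signal of 94.2. A linear model with the 2 groups was fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The prior degrees of freedom were 6.16, and the mean residual SD was 0.195 on the log2 scale. Differences are mutant minus wild-type, and every fold difference is on the log2(signal + 16) scale. The added 16 understates the change of genes with a low signal, but folds average log values, so a fold can also exceed the ratio of the printed means, as it does for Hnf4a. Means and SDs are of the deposited signals.

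Genes were named through the platform annotation table, with symbols updated by gene identifier through a RefSeq table of assembly GRCm38.p6. Of the 45101 probe sets, 34958 were paired with a single gene (18194 genes; 34754 matched by identifier and 204 named as listed), 932 named several genes and 9211 were not listed there and stay unnamed here. No symbol changed. A gene was represented by its tested probe set with the highest mean. Probe set positions in a genome were not analysed here.

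Before the data were examined, 22 gene lists were fixed for nephron structures, other kidney cell types, cells that a dissection could carry along, and pathways. Of their 346 entries, 315 were on the array under a single gene and 280 were tested. List shifts were tested with limma's camera with an inter-gene correlation of 0.01, adjusted over the 22 lists. Alternatives were fry and camera with an estimated correlation, which has little power with so few arrays. Members past the threshold were counted over all tested probe sets and again with p adjusted over the list alone. The atlas list of renal vesicle genes may draw on arrays like these and is no independent evidence of its direction. Genes named in the text were Wnt4, the 20 genes lowest and the 10 highest in the mutant by log2 difference among probe sets past the threshold with no overlap between groups, and up to 4 members of each list with the smallest p. Genes outside this rule were chosen after their values were seen. The alternatives were quantile normalization, arrays centred on their medians, pseudocounts of 1 and 64, no filter, a filter on the lowest 60%, eBayes without a trend or with a robust fit, leaving out probe sets with names ending in _x_at or _s_at, the replicate number as a block, the mean over all probe sets of a gene, and leaving out each array in turn.

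The fit was tested on simulated data with 200 of 27022 probe sets changed, far fewer than the 2920 called in the data. The simulated spread followed the trend of residual variance with signal, with fewer very variable probe sets than the eBayes model assumes. Probe sets were simulated as independent, so the outcomes describe the simulation and need not hold on these arrays. The fit recovered 39% of those changed by 1 on the log2 scale and 70% of those changed by 2, with 0 false calls. A simulated list of 15 shifted genes had a camera p of 1.54e-14, and one of 15 unshifted genes 0.590. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.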

Results

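Gene expression was measured in whole kidneys of mouse embryos at stage E14.5 on 4 arrays, 2 of wild-type kidneys and 2 of kidneys lacking Wnt4. Wnt4 is needed to turn condensed mesenchyme into the renal vesicle, the first epithelial stage of the nephron, so the comparison was designed to find genes expressed in the vesicle and in what forms from it. Across probe sets, the correlation of log2 signals was 0.969 between the wild-type arrays, 0.974 between the mutant arrays and 0.953 to 0.960 between arrays of different genotype. Probe sets are not independent replicates, so these correlations only describe the arrays.

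Wnt4 itself was lower in the mutant at both of its tested probe sets. At the brighter one the signal was 1827 ± 81.3 (SD, n = 2) in wild-type and 339 ± 95.1 (n = 2) in mutant kidneys, a log2 difference of -2.40 ± 0.18 (SE) and a 5.29-fold lower level, with a limma adjusted p of 0.000196. At the dimmer one it was 985 ± 197 against 234 ± 30.1, a 3.98-fold lower level with an adjusted p of 0.000479. The position of these probe sets relative to the disrupted part of the gene was not analysed here.

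The kidneys differed in 2920 of the 27022 probe sets tested (10.8%), 1457 lower and 1463 higher in the mutant. With 1 probe set per gene, 782 genes were lower and 900 higher. A difference of at least 2-fold was found for 987 probe sets, 508 lower and 479 higher, and one of at least 5-fold for 99 lower and 42 higher probe sets. Groups did not overlap in 54.1% of the tested probe sets, against 33.3% by chance. Without the intensity trend the count fell to 858 (433 lower and 425 higher). It also fell without either mutant array, where the spread came from the 2 wild-type arrays alone. A call lost in such a fit need not rest on the mutant array left out.

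Of the 20 genes with the lowest log2 difference, 5 were in the fixed proximal tubule list, 1 in the loop and distal tubule list, 1 in the atlas list of the renal vesicle and 13 in none. The proximal tubule genes were Hnf4a, a transcription factor, Slc34a1, a sodium-phosphate cotransporter, Cubn, an endocytic receptor, Pdzk1, a scaffold protein of the apical membrane, and Keg1. The loop and distal tubule gene was Slc12a1 and the atlas gene Osr2. Slc2a2, Slc39a5, Slc47a1 and Slc27a2, of the solute carrier families, were among those in no list. Tmem52b fell from 961 ± 70.1 to 9.98 ± 0.75, a log2 difference of -5.23 ± 0.26 (adjusted p = 3.52e-05). The zinc finger transcription factor Osr2 went from 1046 ± 100 to 13.8 ± 1.75 (log2 difference -5.16, adjusted p = 3.36e-05). Hnf4a went from 1611 ± 27.4 to 78.4 ± 79.9 (21.5-fold lower, adjusted p = 0.00163), and Slc34a1 was 20.9-fold lower. Fxyd2, a subunit of the sodium pump, went from 2930 ± 133 to 232 ± 0.34 (11.9-fold lower). The other genes of the 20 were Hao2, Sult1d1, Hdc, Asb9, Spink1, Pcp4 and Ttc36, and log2 differences over all 20 ran from -5.23 to -3.20. Of 7 further probe sets for these genes, 6 were called in the same direction, and the exception was a second probe set for Slc12a1. Several mutant signals were near the bottom of the scale, so the sizes and their order depend on the pseudocount: with a pseudocount of 64 the log2 differences of the 20 genes ran from -4.02 to -2.25, and with 1 that of Tmem52b was -6.45. The call of Hnf4a was lost without the intensity trend (adjusted p = 0.0510).

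All 11 tested genes of the renal vesicle list were lower in the mutant, with a median log2 difference of -1.81, that is 3.51-fold. The list includes Wnt4, the gene that the mutants lack, and its fall enters the count, the median and the list test. Jag1 and Dll1, ligands of Notch receptors, were 3.51-fold and 3.74-fold lower. Jag1 fell from 3154 ± 291 to 885 ± 16.7 (adjusted p = 6.07e-05), though 2 further probe sets for it did not pass. The Wnt antagonist Dkk1 fell from 1227 ± 3.85 to 243 ± 14.1 and the LIM homeobox gene Lhx1 from 1154 ± 117 to 181 ± 16.4, 4.80-fold and 5.92-fold lower. All 11 also passed when adjusted over the list alone. The camera adjusted p was 1.26e-15, and the adjusted p was 0.13 with an estimated correlation. Of the 11 tested genes of the atlas list, 9 were lower, among them Osr2, Clec18a (7.62-fold), Irx1 (6.92-fold) and Greb1 (3.76-fold). Sox4 was higher by 1.26-fold and Sfrp2 did not pass, and the counts were also 9 and 1 when adjusted over the list alone. The list median was -1.58 (adjusted p = 1.15e-07, and adjusted p = 0.147 with an estimated correlation).

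Genes of later nephron segments were lower as well. In the proximal tubule list 13 of 19 tested genes were lower and 0 higher (15 lower when adjusted over the list alone), with a median log2 difference of -2.07, and -2.15 to -1.39 when 1 array was left out. Pdzk1 fell from 2110 ± 96.3 to 188 ± 3.54 (10.4-fold), Keg1 from 1500 ± 69.3 to 79.2 ± 0.35 (15.9-fold), and the folate receptor gene Folr1 from 915 ± 69.4 to 205 ± 8.02 (4.21-fold). In the loop and distal tubule list 10 of 16 genes were lower and 0 higher (11 lower when adjusted over the list alone), with a median of -1.25. Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, fell from 1694 ± 352 to 101 ± 27.4 (14.7-fold), the tight junction gene Cldn10 by 6.36-fold, the secreted BMP and Wnt antagonist gene Sostdc1 by 4.87-fold, and the POU-domain gene Pou3f3 by 2.93-fold. Further probe sets for Slc12a1 and Pou3f3 did not pass. In the podocyte list 8 of 17 genes were lower and 0 higher (9 lower when adjusted over the list alone), with a median of -0.46 that ran from -0.61 to -0.28 when 1 array was left out. Podxl, which encodes the podocyte surface protein podocalyxin, fell from 2761 ± 146 to 687 ± 62.0 (3.96-fold), Ptpro by 3.66-fold, Clic5 by 2.70-fold and Rasl11a by 2.43-fold. Camera adjusted p-values were 5.90e-14, 1.23e-10 and 2.14e-05 for the proximal tubule, loop and distal tubule, and podocyte lists. With an estimated correlation the adjusted p was 0.13, 0.159 and 0.147 in the same order. Over all lists, 48 of the 103 called genes had further tested probe sets, 78 in all. Of these, 30 did not pass and 0 were called in the opposite direction. Those that did not pass included every further probe set for Krt8, Eng, Scarb1, Axin2, Ccna2, Trp53inp1 and P4ha1, and 4 of 5 for Sox4.

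**Figure D1:**
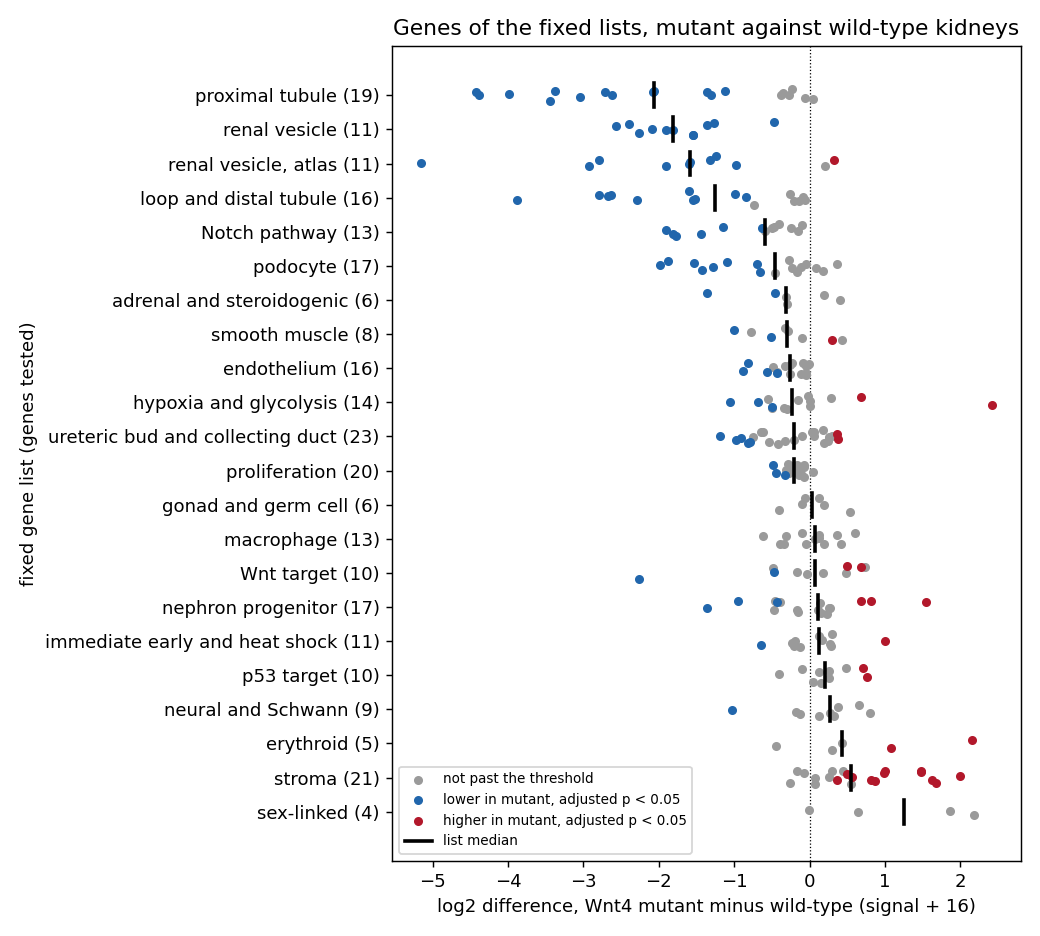
Log2 differences (mutant minus wild-type, signal + 16) of the tested genes of 22 gene lists, 1 point per gene at its probe set with the highest mean, coloured by whether it passed an adjusted p of 0.05, with a black bar at each list median and the number of genes tested beside the list name. Medians run from -2.07 for the proximal tubule list to 0.56 for stroma and 1.26 for the sex-linked list, in which 0 of 4 genes passed.

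Nephron progenitor genes went both ways. Of 17 tested genes, 3 were lower (the homeobox gene Uncx, the progenitor marker Cited1, and Itga8) and 3 higher (Osr1, Traf1 and Crym); Itga8 and Crym were named after their values were seen. Adjusted over the list alone, 5 were lower and 4 higher. Uncx fell from 3208 ± 278 to 1241 ± 165 (2.57-fold) and Cited1 from 2188 ± 364 to 1119 ± 0.83 (1.93-fold). Osr1 was 1.76-fold and Traf1 2.92-fold higher, and both calls were lost without mutant replicate 2 (adjusted p = 0.0625 and 0.136). The calls of Cited1, Osr1 and Traf1 were lost without the intensity trend (adjusted p = 0.0621, 0.0621 and 0.0717). The list median was 0.12 while its mean was -0.01 and camera gave a downward direction (adjusted p = 0.810). When 1 array was left out the median ran from -0.18 to 0.07, so its sign is not settled. The progenitor gene Six2, chosen after its value was seen, had signals of 3328 ± 610 and 2953 ± 399 (adjusted p = 0.524).

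Ureteric bud and collecting duct genes also went both ways. Of 23 tested, 5 were lower (Spry1, Calb1, Emx2, Upk3a and Etv5) and 2 higher (Krt18 and Krt8); Upk3a, Etv5 and Krt8 were named after their values were seen. Adjusted over the list alone, 6 were lower and 2 higher. Spry1, an inhibitor of receptor tyrosine kinase signalling, fell from 2880 ± 73.2 to 1259 ± 33.3 (2.27-fold), and the calcium-binding protein gene Calb1 from 5459 ± 28.8 to 3141 ± 100 (1.74-fold), though 2 further probe sets for Calb1 did not pass. Krt18 was 1.30-fold higher, a call lost without mutant replicate 1 (adjusted p = 0.153) and without mutant replicate 2 (adjusted p = 0.128), with arrays centred on their medians (0.131) and without the intensity trend (0.172). The list median was -0.21 with a camera adjusted p of 0.0272. That call was lost with an estimated correlation (adjusted p = 0.454), without the intensity trend (adjusted p = 0.0619), with fry (adjusted p = 0.0773) and without wild-type replicate 1, where the median was 0.025 (adjusted p = 0.066).

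Stromal genes were higher in the mutant. Of 21 tested genes of the stroma list, 12 were higher and 0 lower (14 higher when adjusted over the list alone), with a median log2 difference of 0.56. Foxd1, the forkhead gene of the cortical stroma, rose from 2211 ± 258 to 6826 ± 158 (3.08-fold, adjusted p = 7.39e-05), and the receptor gene Pdgfra from 2384 ± 33.6 to 6697 ± 220 (2.80-fold). The guidance factor gene Ntn1 rose by 3.21-fold, with a further probe set that did not pass, and Smoc2 by 2.80-fold. The camera adjusted p was 1.01e-10, and the adjusted p was 0.13 with an estimated correlation. On the same arrays 7 of 16 skeletal muscle genes, a list added after the highest genes were seen, were higher, with a median log2 difference of 1.25 (camera p = 1.23e-05, and p = 0.18 with an estimated correlation).

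The 10 genes with the highest log2 difference were Myog, Mfap4, Cadps, Ano4, Myl1, Cdh10, Creb5, Tex15, Adamts6 and Tacr3, with differences from 2.65 to 3.23. Of these, Myog encodes the muscle transcription factor myogenin and Myl1 a myosin light chain of skeletal muscle. Myog rose from 83.2 ± 60.6 to 829 ± 106 (9.41-fold, adjusted p = 0.00177) and Myl1 from 73.1 ± 53.4 to 617 ± 157 (7.72-fold, adjusted p = 0.00344). The call of Myl1 was lost without the intensity trend (adjusted p = 0.0575). Mfap4, a gene of the extracellular matrix, rose from 249 ± 131 to 2266 ± 847 (8.87-fold). Tacr3, the neurokinin 3 receptor gene, rose from 210 ± 6.24 to 1404 ± 5.30 (6.27-fold). Of 4 further probe sets for the 10 genes, only 1, for Tacr3, was called in the same direction. In 8 of the 10 genes, all but Mfap4 and Tacr3, the wild-type mean lay below 94.2, the lowest mean level kept, so the sizes depend on the pseudocount. Log2 differences ran from 1.98 to 2.91 with a pseudocount of 64, and from 2.73 to 3.51 with 1 over the 9 genes that had a value.

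Among cells that accompany the nephron, endothelial genes were lower and embryonic globin genes higher. Of 16 endothelial genes, 4 were lower (Plvap, Cldn5, Emcn and Eng) and 0 higher, with the same counts when adjusted over the list alone. Plvap, a protein of endothelial diaphragms, fell from 1483 ± 10.9 to 837 ± 7.16 (1.76-fold) and Cldn5, a tight junction protein, from 1940 ± 245 to 1042 ± 70.1 (1.84-fold), the latter not past the threshold without the intensity trend (adjusted p = 0.0622). The calls of Emcn and Eng were lost without mutant replicate 1 (adjusted p = 0.202 and 0.136) and without mutant replicate 2 (0.0750 and 0.0857), and that of Eng also without wild-type replicate 1 (0.0615). The median was -0.26 (camera adjusted p = 0.000504, and adjusted p = 0.159 with an estimated correlation), and -0.34 to -0.15 when 1 array was left out. Of 5 erythroid genes, the embryonic globin genes Hba-x and Hbb-y were higher, also when adjusted over the list alone, and 0 were lower. Hba-x rose from 1025 ± 81.0 to 4629 ± 29.6 (4.47-fold) and Hbb-y from 7899 ± 12.1 to 16692 ± 664 (2.11-fold). The other 3 genes, Alas2, Slc4a1 and Tspan33, did not pass, and the median was 0.43 (camera adjusted p = 0.00501, and adjusted p = 0.197 with an estimated correlation). It ran from 0.15 to 0.76 when 1 array was left out.

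With all 4 arrays, camera called none of the lists of other cell types, and fry called 1, the adrenal list (adjusted p = 0.0313). Of 13 macrophage genes 0 passed, with a median log2 difference of 0.07 (camera adjusted p = 0.955). Of 6 gonad and germ cell genes 0 passed (median 0.03, adjusted p = 0.810). Of 8 smooth muscle genes, Tagln (2.01-fold) and Acta2 (1.43-fold) were lower and Tpm2 (1.24-fold) higher, with a median of -0.30 (adjusted p = 0.273). Tagln and Acta2 did not pass without mutant replicate 2 (adjusted p = 0.0753 and 0.187), and Tpm2 did not pass without wild-type replicate 2, mutant replicate 1 or mutant replicate 2 (0.0547, 0.248 and 0.211). Of 9 neural and Schwann cell genes Fabp7 was lower by 2.04-fold, a call lost when any 1 array was left out (adjusted p = 0.101 to 0.128), and the median was 0.27 (adjusted p = 0.498). Of 6 adrenal genes, the corticotropin receptor gene Mc2r (2.56-fold) and Scarb1 (1.37-fold) were lower, with a median of -0.31 (adjusted p = 0.128). Mc2r did not pass without wild-type replicate 1 (adjusted p = 0.148) or mutant replicate 2 (0.0928), and Scarb1 did not pass without wild-type replicate 1 (0.0533), mutant replicate 1 (0.101) or mutant replicate 2 (0.224). The counts in these 5 lists were the same when adjusted over the list alone.

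Among the signalling and growth lists, Notch pathway genes were lower. Of 13 tested, 6 were lower and 0 higher (8 lower when adjusted over the list alone), with a median log2 difference of -0.59 (camera adjusted p = 8.74e-08, and adjusted p = 0.147 with an estimated correlation). Besides Jag1 and Dll1, which the renal vesicle list also holds, Nrarp, a feedback regulator of the pathway, fell from 1833 ± 135 to 666 ± 34.2 (2.71-fold) and its target Hey1 from 1143 ± 108 to 508 ± 1.84 (2.21-fold). Wnt target genes went both ways: Dkk1 and Ccnd1 were lower, Apcdd1 and Axin2 higher, and the other 6 did not pass (2 lower and 3 higher when adjusted over the list alone). The median was 0.07, the mean was -0.09, and camera gave a downward direction (adjusted p = 0.955). Axin2 rose from 544 ± 105 to 877 ± 4.02 (1.61-fold), with a further probe set that did not pass, and Apcdd1 rose by 1.41-fold. Both calls were lost without mutant replicate 1 (adjusted p = 0.0976 and 0.0630) and without mutant replicate 2 (0.100 and 0.126), and that of Ccnd1 without mutant replicate 2 (0.0926).

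Proliferation genes were slightly lower: of 20 tested, 3 were lower (Rrm2, Ccna2 and Pcna) and 0 higher, and 8 were lower when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, was 1.40-fold lower, Ccna2 1.36-fold and Pcna 1.25-fold. The list median was -0.20 (camera adjusted p = 2.89e-05, and adjusted p = 0.165 with an estimated correlation). Without mutant replicate 2 the adjusted p was 0.0536 for Rrm2, 0.137 for Ccna2 and 0.122 for Pcna, without mutant replicate 1 it was 0.0520 for Ccna2 and 0.264 for Pcna, and without wild-type replicate 1 it was 0.0512 for Pcna. Of 10 p53 target genes, Cdkn1a (1.70-fold) and Trp53inp1 (1.64-fold) were higher and 0 lower (3 higher and 1 lower when adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.0816). Trp53inp1 did not pass without mutant replicate 1 (adjusted p = 0.0849), and neither gene passed without the intensity trend (0.0565 and 0.134).

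Of 14 hypoxia and glycolysis genes, Egln3, Ldha and Ndrg1 were lower and Pdk1 and P4ha1 higher (5 lower and 3 higher when adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.275). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose from 308 ± 49.1 to 1713 ± 177 (5.36-fold, adjusted p = 7.82e-05), with 1 of 2 further probe sets not past the threshold, while Egln3, a prolyl hydroxylase gene induced by low oxygen, fell by 2.08-fold. The call of Egln3 was lost without the intensity trend (adjusted p = 0.0625), and its further probe set did not pass (0.0632). Ldha was 1.41-fold lower, not past the threshold without mutant replicate 1 (adjusted p = 0.0648) or mutant replicate 2 (0.0618), and P4ha1 was 1.61-fold higher, not past it without mutant replicate 2 (0.0859). Of 11 immediate early and heat shock genes, Jun was higher, 1356 ± 165 against 2729 ± 138 (2.01-fold), and Egr1 lower by 1.57-fold, a call lost without mutant replicate 1 (adjusted p = 0.0774). The counts of that list were the same when adjusted over the list alone. Its median was 0.13 while camera gave a downward direction (adjusted p = 0.955).

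Sex-linked genes differed between the wild-type arrays. Xist, the RNA of the inactive X chromosome, had a signal of 207 on wild-type replicate 1 and 7361 on replicate 2, and 5709 and 5863 on the mutant arrays. The Y-linked gene Eif2s3y had a signal of 568 and 2.80 on wild-type replicates 1 and 2 and 465 and 285 on mutant replicates 1 and 2. None of the 4 tested genes of this list (Xist, Eif2s3y, Kdm5d and Uty) passed the threshold, also when adjusted over the list alone, and the list median was 1.26 (camera adjusted p = 0.473). The labels give sex as unknown for every pool. By these signals wild-type replicate 1 had the pattern of male tissue and wild-type replicate 2 that of female tissue, while both mutant arrays carried both signals. With arrays centred on their medians Xist passed (limma adjusted p = 0.0136), though its log2 difference hardly moved, from 2.18 to 2.19. That gain came from the variance fitted under this setting, not from a larger difference. All 4 passed without 1 of the wild-type arrays. Without wild-type replicate 1 the log2 difference was -0.35 for Xist (adjusted p = 0.0241), 4.34 for Eif2s3y (1.47e-05) and 2.35 for Kdm5d (0.00272). Without wild-type replicate 2 it was 4.70 for Xist (1.29e-10) and -1.05 for Kdm5d (0.0410), and Uty was lower (0.0368).

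**Figure D2:**
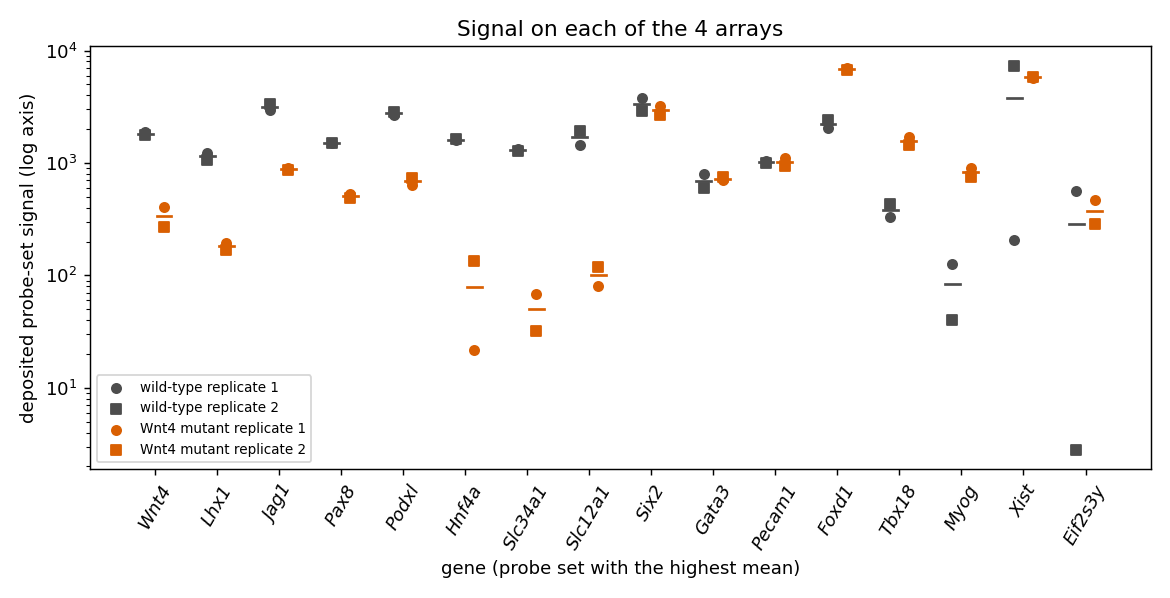
Deposited probe-set signal (log axis) of 16 genes on each of the 4 arrays, with circles for replicate 1, squares for replicate 2 and a line at each group mean; Pax8, Six2, Gata3, Pecam1 and Tbx18 were chosen after their values were seen. Wnt4 lies at 1885 and 1770 on the wild-type arrays and 406 and 272 on the mutant arrays, Foxd1 is higher on both mutant arrays, and the wild-type arrays differ in Xist and Eif2s3y.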

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

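The alternatives were fixed before the data were examined, except the count of genes whose probe sets all passed, which was chosen after seeing the data. Leaving out an array leaves 1 array in a group, which is then assumed to vary like the other group. Of the 111 genes followed over the alternatives, 75 kept their direction and their side of the threshold in every alternative that gave them a value and 36 did not in at least 1. A pseudocount of 1, the filter on the lowest 60% and leaving out _x_at and _s_at probe sets gave no value for 6, 29 and 13 of them. Signal near background limits the size of the low values: over the 20 lowest genes log2 differences ran from -4.02 to -2.25 with a pseudocount of 64, and from -6.45 to -3.43 with 1 over the 15 that had a value. The log2 difference of Wnt4 ran from -2.68 to -2.13 over 14 alternatives, with an adjusted p of at most 0.0215. Of the followed genes, 26 lost their call without the intensity trend and 1 (Pcna) under quantile normalization. With arrays centred on their medians 11 lost it (Krt18, Acta2, Tpm2, Emcn, Eng, Scarb1, Ccnd1, Apcdd1, Rrm2, Ccna2 and Pcna). Their log2 differences hardly moved, that of Krt18 from 0.38 to 0.40, so the losses came mainly from the variance fitted there. Without a filter 11 lost it (Traf1, Tagln, Acta2, Tpm2, Eng, Fabp7, Mc2r, Scarb1, Axin2, Pcna and Trp53inp1).

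Without the intensity trend 858 probe sets were called, 433 lower and 425 higher, of which 823 were among the 2920. With the lowest 60% left out, 599 differed by at least 2-fold, since fewer were tested. Leaving out each array gave 1479 to 3927 called probe sets, 815 to 1877 lower, 664 to 2050 higher and 893 to 1166 by at least 2-fold. The lowest counts of called, lower and higher probe sets came without mutant replicate 1. Without either mutant array the spread came from the 2 wild-type arrays alone, so these counts reflect how those 2 arrays differ. Of 6010 genes with several probe sets, 886 were called at the probe set with the highest mean and 207 had all probe sets past the threshold in 1 direction.

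Limma's camera with an estimated correlation called 0 of the 22 lists, against 11, although 6 had an unadjusted p under 0.05. The estimate lay below the preset 0.01 for proximal tubule (-0.003), stroma (-0.045), podocyte (-0.03), the atlas list (-0.064), endothelium (-0.014) and erythroid (-0.199). It lay above 0.01 for renal vesicle (0.034), loop and distal tubule (0.134), ureteric bud (0.101), Notch (0.03) and proliferation (0.039). High correlation between genes was therefore not what removed all of the calls. Fry, which tests only whether the genes of a list move one way, called 12, 10 of them among the 11. The medians are the reported ones, -1.81 for renal vesicle, -1.58 for the atlas list, -0.46 for podocyte, -2.07 for proximal tubule, -1.25 for loop and distal tubule, -0.21 for ureteric bud, 0.56 for stroma, -0.26 for endothelium, 0.43 for erythroid, -0.59 for Notch and -0.20 for proliferation. The ureteric bud list (-0.21) also lost its call without the intensity trend and with fry, and its median without each array ran from -0.35 to 0.025. Calls were gained by the p53 list without a filter (0.26, camera adjusted p = 0.0252) and with fry (0.21). The adrenal list gained one with fry (-0.31, adjusted p = 0.0313), and the sex-linked list with arrays centred on their medians (1.27). The sex-linked median was 1.26 before centring, so its gain did not come from a larger shift. When 1 array was left out, the signs of the nephron progenitor, sex-linked, macrophage, gonad, immediate early and Wnt target medians changed in at least 1 case, none of these lists being called. The smooth muscle median ran from -0.47 to -0.17 and passed without mutant replicate 1 (adjusted p = 0.0165). The cause was not tested. The log2 difference of Xist reversed to -0.35 without wild-type replicate 1 and was 4.70 without wild-type replicate 2, and that of Kdm5d was 2.35 and reversed to -1.05. These follow from the unlike signals of the 2 wild-type arrays.

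With the replicate number as a block (replicate block), 2913 probe sets were called, 1409 lower and 1504 higher, and 2653 were shared with the fit without it. Pcna, Tpm2 and Fabp7 no longer passed. Arrays with the same number did not deviate together (correlation of deviations -0.02), so the numbers were not taken to pair the arrays.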

Other observations

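Tests in this part were chosen after the result was seen, except those of probe mismatch, of the neighbours of Wnt4, of muscle genes and of the other splits of the arrays.

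Families of genes that share a name were also compared, only some of whose members are in a fixed list. The name patterns were narrowed once after first results were seen, which took 7 genes from the solute carriers (Slc51a and Slc51b, which are solute carriers, among them), 4 from ADAMTS and 3 from Hox. With the first patterns 30 of 251 solute carrier genes were lower and 7 of 18 ADAMTS genes higher (adjusted p = 0.000796 for each), and the collagen and Zfp counts were the same. The p-values below do not account for this choice. Of 36 collagen genes tested, 11 were higher in the mutant (30.6%, against 6.6% of other genes; Fisher's exact test, adjusted p = 0.000263 over 18 family tests in 9 families). The 3 collagen genes of the stroma list, Col1a1, Col1a2 and Col3a1, were not among the 11 at their probe sets with the highest mean. A further probe set for Col3a1 was 1.81-fold higher (limma adjusted p = 0.00104), while those for Col1a1 and Col1a2 did not pass. The 11 included Col6a1 (2.11-fold), Col6a2 (2.08-fold), Col6a3 (1.73-fold) and Col5a1 (1.59-fold). Col4a1 and Col4a2, collagens of basement membranes, were each 1.53-fold lower. The collagen count was 10 to 11 higher under quantile normalization or centring on medians and 7 to 13 without each array, and it passed in each case (adjusted p at most 0.00185). Of 14 ADAMTS metalloproteinase genes 6 were higher and 2, Adamts16 and Adamts1, lower. The share of higher genes (42.9%, adjusted p = 0.00101) no longer passed without mutant replicate 1 (3 genes, adjusted p = 0.0585) or mutant replicate 2 (2 genes, adjusted p = 0.206). Of 244 solute carrier genes, 28 were lower (11.5%, against 5.7% of other genes; adjusted p = 0.00331) and 12 higher, with 28 and 26 lower under the scalings. The excess of lower solute carrier genes did not pass without wild-type replicate 1 (adjusted p = 0.116), wild-type replicate 2 (0.225) or mutant replicate 1 (0.0585). Of 300 zinc finger genes named Zfp, 4 were lower (1.3%, against 5.9% of other genes; adjusted p = 0.00101) and 22 higher, with 4 and 3 lower under the scalings, and the low share did not pass without mutant replicate 1 (adjusted p = 0.149) or mutant replicate 2 (0.179).

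Some genes, chosen after their values were seen, differed between their own probe sets. Phgdh, an enzyme of serine synthesis, had signals of 463 and 409 on the wild-type and 4478 and 4489 on the mutant arrays at 1 probe set (9.97-fold higher). At 2 of its other probe sets it fell by 0.48 and 0.45 on the log2 scale, calls lost under some scaling or without some array (adjusted p up to 0.120 and 0.257), and at 1 it did not pass. Paip1 was 11.7-fold and 17.6-fold higher at 2 probe sets and did not pass at 1 (log2 difference -0.12). At the first 2 the wild-type signals were 88.2 and 63.4, and 13.8 and 47.8. All lay below 94.2, the lowest mean level kept, so these sizes depend on the pseudocount. The noncoding RNA gene Meg3 was higher at 5 of 10 probe sets, by 16.8-fold at 1 of them, and did not pass at the other 5. Of the 5 calls 1 was lost under some scaling or without some array (adjusted p up to 0.0565). A further embryonic globin gene, Hbb-bh1, was higher at all 3 of its probe sets (4.41-fold to 8.75-fold). At the probe set with the largest fold the wild-type signals were 13.1 and 83.0, below the 94.2 of the lowest mean level kept. Its log2 difference ran from 2.25 to 4.01 under the scalings and without each array.

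Of the 1682 genes called, 246 were at least 2-fold higher in the mutant, 235 of them in none of the fixed lists, and sequence differences between CD-1 and 129 mice may have changed how well some probes bind. A mismatch under 1 probe set would leave the other probe sets of a gene near 0, but in the 106 of these genes that had others, the others moved by a median of 0.6544 of the leading difference (95% bootstrap interval 0.515 to 0.702). As a group these 106 genes were thus not changed at 1 probe set alone, though this need not hold for each of them. They were chosen by the probe set with the highest mean, and weaker binding in 1 strain lowers that mean. Phgdh and Paip1, each far higher at only some probe sets, were left out this way. The ratio therefore cannot weigh against mismatch beyond these genes. In 23 of them (21.7%) the ratio was 0.25 or less. Among the genes at least 2-fold lower that had other probe sets, this share was 17% (Fisher's exact test, p = 0.476). Whether the probe sets of a gene overlap in sequence was not analysed here. The rest of the 246 genes at least 2-fold higher had no other tested probe set, so mismatch was not tested there. A 129 segment around Wnt4 on an otherwise like background is argued against by an odds ratio of 0 for such genes among the 200 tested neighbours of Wnt4 (0 of 200 against 246 of 13231 elsewhere; upper 95% bound 0.99; Fisher's exact test, p = 0.0552, adjusted 0.110; neighbours from assembly GRCm38.p6), and by 0.688 for all called genes (18 of 200; 95% interval 0.398 to 1.12; p = 0.16), both bounds lying below the 1.5 set beforehand. A strain difference in expression spread over the genome cannot be told apart from the effect of the mutation for these 235 genes, since every wild-type array is labelled CD-1 and every mutant array 129.

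Genes of the stroma were higher while the nephron lists were lower, and loss of nephron cells could raise the share of every remaining cell type. The stroma median exceeded that of 52 ureteric bud, endothelial and macrophage genes by 0.7129 on the log2 scale (permutation of genes, p = 1e-05). That is the smallest p that 100000 permutations can give. A shared rise alone would move these lists alike, and their medians were -0.21, -0.26 and 0.07 in the same order. Those medians were known when the comparison was chosen. The ureteric bud list also shares Emx2 with the atlas list of the renal vesicle. A fall in these lists for another reason could mask a shared rise, so the comparison cannot exclude one. The permutation p-values measure the scatter between genes, not between pools, so they describe these arrays only. Against these lists singly and the nephron progenitor list the difference was 0.76, 0.82, 0.49 and 0.44 (permutation p = 1e-05, 0.00026, 0.0133 and 0.0368; adjusted over 5 tests 2.5e-05, 0.000433, 0.0166 and 0.0368). The lowest stroma median under the scaling alternatives was 0.5597. The deposited arrays already shared a common level, with a median log2 difference of -0.0109 over all tested probe sets. These alternatives could therefore move the stroma median only a little, and they cannot decide whether scaling raised it. A change in the stroma itself stays open as a hypothesis, as does tissue carried along with the mutant kidneys. On the same arrays 7 of 16 tested skeletal muscle genes were higher and 0 lower (camera p = 1.23e-05, and p = 0.18 with an estimated correlation). A strain difference in the 12 higher stroma genes cannot be told apart from an effect of the mutation in this design.

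Because Myog and Myl1 were among the highest genes, 25 further skeletal muscle genes, 0 of them in a fixed list, were written down before their values were seen. Of the 16 tested, 7 were higher and 0 lower, with a median log2 difference of 1.2536 (95% bootstrap interval 0.25 to 1.59; camera p = 1.23e-05, and p = 0.18 with an estimated correlation), and 0.84 to 1.51 under the scalings and without each array. Tnnt2 rose 5.22-fold, Myod1 3.02-fold and Tnni1 2.99-fold, while 9 did not pass (Tnnc2, Actn2, Cdh15, Acta1, Ckm, Ttn, Tnni2, Myl4 and Myom1; adjusted p from 0.0505), and the highest signal of any of the 16 on a mutant array was 738. The median difference between the 2 mutant arrays was -0.0296, so the signal was not confined to 1 mutant pool, and wild-type replicate 1 exceeded replicate 2 by a median of 0.29. Muscle tissue attached to the mutant kidneys is a possible explanation, and expression of these genes within the mutant kidney, or a strain difference, stays untested.

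The other 2 ways to split the 4 arrays into 2 and 2 called at most 0 probe sets, against 2920 for the real split, which 1 of the 3 splits reached. With 3 splits a share under 0.05 cannot be reached. Each other split also puts 1 wild-type and 1 mutant array in the same group. Differences between the genotypes then enter the spread, so the low counts follow from them and add no evidence.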
